A study of Mus musculus with 10 samples.

How the data were processed

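ChIP-seq libraries were made from mouse ES cells of strain C57BL/6. Per the labels' protocols, cells were fixed with 1% formaldehyde for 5 min, 10 µg of antibody was used per immunoprecipitation, and the recovered DNA was sheared again to about 150 bp. The 10 libraries form 10 groups of 1: the GFP immunoprecipitation and the input of knockout cells rescued with AVI-EGFP-PRDM14, the same pair from knockout cells rescued with EGFP alone, and H3K27me3, SUZ12 and input libraries of wild-type and knockout cells. The 2 files analysed both belong to the GFP immunoprecipitation of the PRDM14-rescued cells. The other 9 libraries were not analysed here, so no comparison between groups was made.

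The deposited peak table gives, for each peak, an interval, a peak position, an enrichment, a width, a maximum named for the immunoprecipitation and a flag, per the file headers. The genome build is mm9, per the submitters' processing notes. The aligner, the peak caller, the control library and the total read depth are not given in the sources used here. The authors deposited the enrichment as a ratio, which was used only to describe and rank peaks within the list. The deposited height is a read pileup signal, a whole number in every peak, and is not normalized. The flag is a score in the authors' table that equals 3 in every peak and was not used. The second deposited file is a BED list, whose 3608 intervals were identical to those of the table (overlap of at least 1 bp, or of 50% of both intervals, gave the same 3608). Coordinates are printed as deposited. Starts lie on a 10 bp grid and the width equals end minus start in every peak, so whether positions count from 0 or 1 was left open. All but 2 peaks had a height of at least 51 reads, the exceptions being 45 and 50, and 1 peak had an enrichment under 3.

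The values show how the enrichment was scaled. Within a chromosome, the largest quotient of enrichment and height was taken as that chromosome's factor. After division by it, every enrichment was a fraction with a denominator of at most 60 (tolerance 0.001), and 2749 of the 3608 values were whole, against 0.2% expected by chance. The authors' enrichment therefore carried a factor that differed between chromosomes, from 0.95 to 1.30, and had a small whole number below it. In lowest terms a denominator of 1 can also stand for a larger one that cancelled, and it can be a read count or a floor. The precision of single enrichments and heights was not measured.

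Clustering was measured as the share of peaks with another peak position within 10 kb and was compared with 1000 random placements of the peaks between the first and last peak of their chromosome. The densest windows of 1 and 5 Mb on a fixed grid were compared with the densest window of the same placements (one-sided). Medians were compared with two-sided permutation tests of 100000 resamples, and peak counts per chromosome were correlated with the position of the last peak by Pearson's and Spearman's coefficients with 100000 permutations. Wilson intervals for shares and exact Poisson intervals for counts per Mb are at the 95% level and cover counting error only. They treat peaks as independent, which neighbouring peaks are not, so they can be too narrow. Since the list comes from 1 library, p-values describe the arrangement of its peaks and say nothing about variation between samples. The procedures were tested on simulated lists of 3608 peaks. Of 40 random lists, 0 passed the clustering test at 0.05, each run with fewer placements than the 1000 above. These lists were drawn by the rule that the test itself uses, so a low pass rate was fixed in advance. It does not show that uniform placement suits real peaks. A list with 200 peaks moved next to another gave a permutation p of 0.002. A window with 30 planted peaks was found, which is more than the 14 peaks of the densest 1 Mb window here. The factors of all 20 chromosomes were recovered, but each simulated chromosome held peaks set at the factor times the height. That recovery was fixed in advance and does not test whether the deposited list holds such peaks. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1 were used.

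The rule for the sites named in the text was fixed before the data were examined: where genes could not be placed on the build of the peaks, the 10 highest peaks by the authors' enrichment are named by position. The tallest peaks, the densest windows and the short peaks were singled out after their values were seen. The 20 gene lists fixed beforehand, the distance to transcription start sites, the promoter share and the search for a PRDM14 sequence motif need mm9 annotation or sequence and were not run, and their results are therefore not reported. Alternatives were other neighbour distances, only peaks at or above the median enrichment, other overlaps and the leaving out of chromosomes. Merging of peaks closer than 1 kb, leaving out peaks narrower than 500 bp, leaving out the X chromosome, the median split by height, the division of the enrichment by the chromosome factor, the window tests and the comparison of clustered with isolated peaks were added after the data were seen.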

Results

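The series examined where PRDM14, a PR-domain zinc finger protein of pluripotent and primordial germ cells, sits on chromatin in mouse embryonic stem (ES) cells, and how H3K27me3 and SUZ12 are distributed with and without Prdm14. H3K27me3 is the histone mark deposited by Polycomb repressive complex 2, and SUZ12 is a core subunit of that complex. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on 10 libraries, 6 of them immunoprecipitated and 4 of them input, each the only member of its group. Prdm14 knockout cells had been rescued with either an AVI-tagged EGFP fusion of PRDM14 or EGFP alone, and an antibody against GFP was used on both. Peak calls from the GFP immunoprecipitation of the PRDM14-rescued cells were analysed. The other 9 libraries were not analysed here, so no binding level was set against the EGFP-only cells and no wild-type to knockout comparison of H3K27me3 or SUZ12 was made. The total read depth of the library was not given in the sources used here. There was no replicate, and every value below describes this 1 peak list.

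PRDM14 peaks were called at 3608 regions, none of which overlapped, on the 19 autosomes and the X chromosome. Between neighbours, 94 gaps were under 1 kb, and merging across these left 3514 peaks, so the regions need not all be distinct binding sites. The regions were narrow, with a median width of 809 bp and quartiles of 699 and 979 bp. The median height, which is the highest pileup of immunoprecipitated reads within a region, was 83 reads, and the quartiles were 62 and 133 reads. Heights had a long upper tail that reached 1226 reads. The median enrichment over the control, as given by the authors, was 55.8, with quartiles of 32.1 and 86.8. The weakest region had an enrichment of 2.58 and the strongest 830.3. The position of the peak lay a median of 75.5 bp from the midpoint of its interval. Taller peaks were wider (Spearman's rho = 0.88 across 3608 peaks, which are not independent replicates).

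The most enriched site lay on chromosome 6 at 70913550 to 70916249 (mm9), with an enrichment of 830.3, a height of 1109 reads and a width of 2699 bp. The second lay on chromosome 1 at 90565000 to 90566599, with an enrichment of 736.9 and a height of 734 reads. The third was on chromosome 14 at 49774780 to 49775979, where the enrichment was 663.04 and the height 557 reads. Chromosome 11 held 2 of the 10 most enriched sites. That at 71315230 to 71316529 had an enrichment of 631.05, and that at 20130220 to 20131929 had an enrichment of 553.1. Chromosome 8 also held 2, which tied at an enrichment of 567.2. Of these, the site at 93374980 to 93376469 rose to 1155 reads, whereas the site at 111252890 to 111254619 rose to 558 reads. The remaining members were on chromosome 2 at 127539890 to 127541139 (enrichment 579.9), on chromosome 13 at 98052380 to 98053569 (enrichment 556.6) and on the X chromosome at 100667190 to 100668539 (enrichment 543.4, height 775 reads). The enrichment carried a factor that differed between chromosomes, and division by it kept 8 of these 10 sites among the first 10 and moved the X site from rank 10 to rank 3. Genes and transcript features at these positions are not named, because the annotation at hand (GRCm38) is of another build than the peaks (mm9).

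Ranking the same sites by height gave a different set. The tallest peak of the list lay on chromosome 1 at 13074380 to 13076049 and reached 1226 reads, but its enrichment of 216.2 placed it at rank 151. The peak on chromosome 5 at 127235010 to 127236309 was at rank 3 by height, with 1131 reads, and at rank 344 by enrichment, with 148.02. A further peak on chromosome 4 at 137561370 to 137562609 reached 1045 reads and an enrichment of 147.1, at rank 347. Only 2 sites, those on chromosome 6 and on chromosome 8 at 93374980, were in both lists of 10, and 44 sites were in both lists of 100. Across all peaks, enrichment and height were related with Spearman's rho = 0.63. Enrichment values were whole multiples of 1 factor per chromosome, or simple fractions of it. In lowest terms, the denominator of that fraction was 1 in 2749 peaks (76.2%, 95% Wilson interval 74.8% to 77.6%), 2 in 402, 3 in 254 and above 3 in 203. All 10 of the most enriched sites had a denominator of 1, in a ranking by an enrichment of which the denominator is part. In lowest terms a 1 need not be the control count, since a larger denominator can cancel. Only 231 peaks had an enrichment equal to the factor times the height, and the median was 48.7% of that product.

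**Figure D1:**
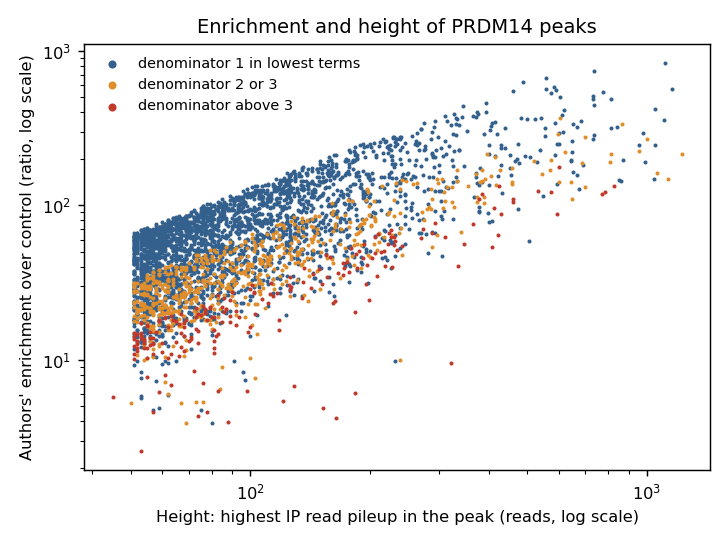
Authors' enrichment over control (vertical, log scale) against the height of each of the 3608 PRDM14 peaks in reads (horizontal, log scale), coloured by the denominator of the enrichment in lowest terms. The upper edge is formed by peaks with a denominator of 1, and the 3 colours overlap below it. This edge follows from the definition of the factor as the largest quotient of enrichment and height on a chromosome.

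PRDM14 peaks were spread over all 20 chromosomes, but unevenly for their length. Chromosome 11 was the most densely occupied, with 269 peaks or 2.21 per Mb (95% exact Poisson interval 1.95 to 2.49), and chromosome 5 followed with 276 peaks or 1.82 per Mb (1.61 to 2.04). Among autosomes, chromosome 14 had the lowest density, 0.99 per Mb from 122 peaks (0.82 to 1.19). The X chromosome carried 98 peaks, or 0.59 per Mb (0.48 to 0.72), which was below every autosome and 0.41 of the autosomal median of 1.45 per Mb. These intervals cover counting error only and treat peaks as independent. Lengths were taken as the position of the last peak on each chromosome. The number of peaks rose with this length (Pearson's r = 0.64, permutation p = 0.00237; Spearman's rho = 0.60, permutation p = 0.00568; 20 chromosomes, two-sided). The Benjamini-Hochberg adjusted values over these 2 tests were 0.00474 and 0.00568. Without chromosomes 1 and 19, the farthest from the median length, r was 0.52 (permutation p = 0.0266). Without the X chromosome r was 0.79.

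**Figure D2:**
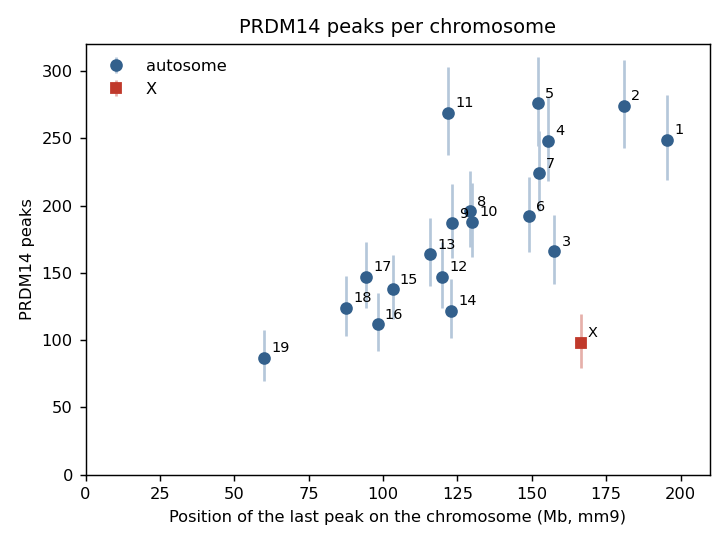
Number of PRDM14 peaks (vertical) against the position of the last peak in Mb (horizontal) for each chromosome, with 95% exact Poisson intervals as bars. The X chromosome, with 98 peaks, lies below autosomes of like length, and chromosome 11, with 269 peaks, lies above them.

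The median height of the peaks on the X chromosome was 90 reads against 83 reads on autosomes (difference 7 reads, two-sided permutation p = 0.322), and their median enrichment, on the authors' scale, was 57.8 against 55.5 (permutation p = 0.698). Divided by the factor of each chromosome, the median enrichment was 61 on X against 46 on autosomes (permutation p = 0.00066). These permutations treat single peaks as independent, although X is 1 chromosome with 1 factor, so the p-values may be too small. The enrichment factor of the X chromosome was 0.95, whereas the 19 autosomal factors ran from 1.10 on chromosome 7 to 1.30 on chromosome 11. The denominator of the enrichment was 1 in 92.9% of X peaks (95% Wilson interval 86.0% to 96.5%), against 69.6% to 82.3% on single autosomes. The enrichment divided by the factor depends on this denominator, which in lowest terms does not give the control count. The median of 61 therefore does not show stronger binding on X.

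PRDM14 sites lay in clusters along the chromosomes. Of the 3608 peaks, 583 (16.2%, 95% Wilson interval 15.0% to 17.4%) had another peak within 10 kb. In 1000 random placements between the first and last peak of each chromosome, this share averaged 2.95% and did not exceed 4.38% (two-sided permutation p = 0.002, the smallest these placements can give). Within 50 kb, 36.4% of peaks had a neighbour, against 13.8% at random (permutation p = 0.002). Uniform placement takes no account of genes, sequence gaps or regions where reads cannot be mapped uniquely. Clustered peaks were slightly taller than isolated ones, with medians of 89 and 81 reads (583 and 3025 peaks, two-sided permutation p = 0.0239). When neighbours were taken within 50 kb, the medians were 84 and 81 reads (permutation p = 0.270). When peaks closer than 1 kb were merged, keeping the tallest interval, the medians were 90 and 83 reads (permutation p = 0.0681). The permutations treat single peaks as independent, whereas clustered peaks are neighbours of each other, so the p-values for height may be too small.

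The distal part of chromosome 5 stood out at the scale of 5 Mb. Its window from 135 to 140 Mb held 38 peaks, with a median enrichment of 65.4 and a median height of 80 reads. The densest window of a random placement held a median of 18 and at most 29 peaks (permutation p = 0.001, the smallest these placements can give). Next came 24 peaks at 85 to 90 Mb of chromosome 11. At the scale of 1 Mb, 3 windows held more peaks than any window of any random placement (at most 12). The window at 136 to 137 Mb of chromosome 5 held 13 peaks with a median enrichment of 60.1, and the window at 88 to 89 Mb of chromosome 11 held 13 with a median enrichment of 53.2. The window at 38 to 39 Mb of chromosome 7 held the most, 14, but these had a median enrichment of 13.03, and 8 remained after peaks closer than 1 kb were merged. After this merging the densest window was that on chromosome 5. Strong sites were gathered at 135 to 136 Mb of chromosome 4, where 11 peaks had a median enrichment of 113.1 and a median height of 110 reads. At 19 to 20 Mb of chromosome 8, 11 peaks had a median enrichment of only 8.32, and 7 of them were narrower than 500 bp.

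**Figure D3:**
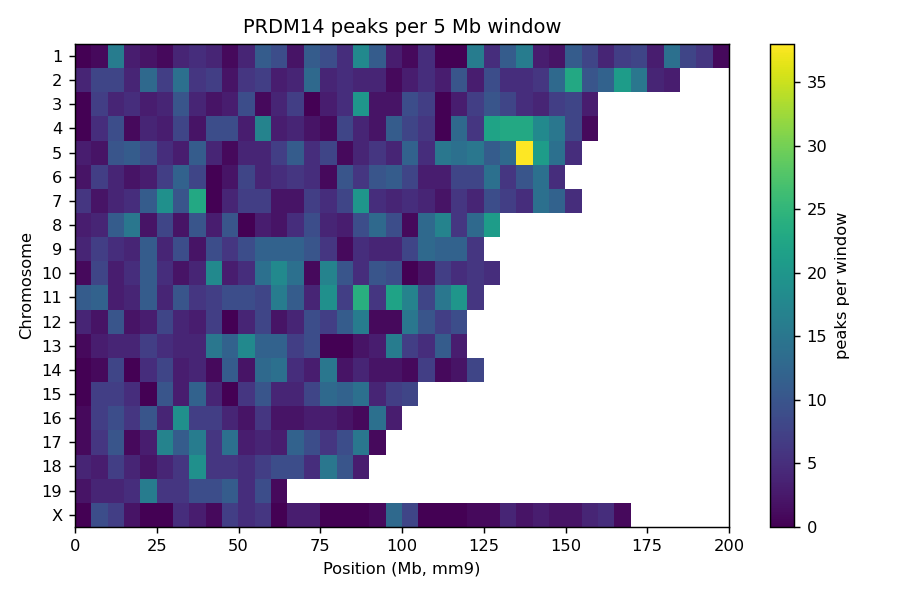
Number of PRDM14 peaks per 5 Mb window (colour) by position in Mb (horizontal, mm9) and chromosome (vertical), with white beyond the last peak of each chromosome. The window with the most peaks, 38, lies at 135 to 140 Mb of chromosome 5.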

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

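Of 26 alternatives with a test, 23 kept the direction and the side of the threshold, although the densest 1 Mb window was then not always the same window. The median enrichment of X peaks exceeded that of autosomal peaks past the threshold once divided by the chromosome factor (difference 15, against 2.23 as deposited). The division removes the authors' scaling, and a larger share of X than of autosomal peaks had a denominator of 1, so this does not show stronger binding on X. The test also treats peaks of 1 chromosome as independent. A further 5 alternatives had no test. The overlap settings left 3608 shared intervals, merging left 3514 peaks and the short-peak filter 3578. Keeping only peaks at or above the median enrichment left 1804 of the 3608 peaks, by construction. The share of peaks with a neighbour stayed above every random placement in all 5 alternatives, from 10.7% (upper part by height) to 36.4% (within 50 kb). Merging peaks closer than 1 kb took it from 16.2% to 11.9%. The correlation of peak number with chromosome length stayed past its threshold in all 5 alternatives, with Pearson's r from 0.52 to 0.79 and Spearman's rho from 0.48 to 0.78. For the height of clustered peaks, the difference of 8 reads became 3 within 50 kb and 7 after merging, neither past the threshold. It was 24 among peaks at or above the median enrichment and 9 without peaks narrower than 500 bp, both past it. These height tests treat neighbouring peaks as independent. The densest 5 Mb window was that on chromosome 5 in all 3 alternatives, whereas the densest 1 Mb window moved from chromosome 7 to chromosome 5 after merging (13 peaks) and to chromosome 4 at or above the median enrichment (9 peaks). Without peaks narrower than 500 bp, the windows on chromosomes 5, 7 and 11 tied at 13 peaks. No replicate could be left out, and no paired analysis was possible because each group held 1 library. Alternatives on transcription start sites, promoters, motif and gene lists were not run, since they need mm9 annotation or sequence. Merging, the short-peak filter, the division by the factor, the height split, the leaving out of X and the alternatives for windows and clustered peaks were chosen after seeing the data.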

Other observations

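A set of 30 peaks narrower than 500 bp differed from the rest of the PRDM14 list. They fell into 16 windows of 1 Mb: 7 lay at 19 to 20 Mb of chromosome 8, 4 at 15 to 16 Mb and 3 at 14 to 15 Mb of chromosome 5, 3 at 3 to 4 Mb of chromosome 9, and the rest singly or in a pair. Another peak lay within 50 kb of 22 of the 30 (73.3%), against 36.1% of the other 3578 peaks. The median enrichment was 7.36, against 41.7 in 300 other peaks of like height (65.5 and 63.5 reads in the median). Many of the 30 are neighbours of each other and not independent, so no p is given for these differences. The peak with the lowest enrichment of the whole list, 2.58, was one of them (chromosome 8, 19968340 to 19968669). On chromosome 9, the short peak at 3027050 to 3027399 rose to 321 reads with an enrichment of only 9.50.

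All tests of explanations below were chosen after the data had been seen. Whether the short peaks were short only because they were low cannot be told from their width at matched height (a difference in medians of -325 bp), since they had been chosen by width. A candidate explanation is that reads pile up at these places in the control too, as in repeated sequence. A denominator above 1 was found in 43.3% of them, against 27.7% of the height-matched peaks. This cannot decide, since the denominator is itself part of the enrichment and the peaks share places. The denominator of 1 in 17 of the 30 does not show low control coverage either, since a larger one can have cancelled. No biological explanation was tested.

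The X chromosome had few peaks and the lowest enrichment factor. If reads in peaks lowered the factor of peak-rich chromosomes, X, the poorest in peaks, would have a high factor. Its factor was 0.947 (lowest autosome 1.10), which goes against this cause but restates the pattern and is no separate test. Over the 19 autosomes, no fall of the factor with peaks per Mb was detected (Spearman's rho = 0.007, permutation p = 0.979). Without chromosomes 14 and 11, the farthest from the median density, rho was -0.14 (permutation p = 0.577). This cannot decide, since peaks per Mb do not measure the share of reads in peaks and a weak fall could be missed with 19 chromosomes. Control coverage as high on X as on autosomes is argued against, since 92.9% of X peaks had a denominator of 1 and the highest autosome had 82.3%. That share is only an indirect measure of control coverage, since a denominator of 1 can be a floor or a larger one that cancelled. Fewer X fragments in the immunoprecipitated library, together with the same minimum height for every chromosome, may explain the low count. The density on X, 0.589 per Mb, falls within the 0.37 to 0.89 per Mb of autosomes counted at 2 times the minimum height. This cannot decide, since the multiple presumes a level of X fragments that no label gives and the autosomal range is wide. With X also counted at 2 times the minimum height, its density was 0.25 per Mb, below every autosome. Fewer binding sites on X or less uniquely mappable sequence would also lower the count and were not tested. A different X copy number in the cells of the immunoprecipitation and of the control (X factor 0.777 of the autosomal median) cannot be told apart from other causes of the low factor, because the control library is not named.

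Clustered peaks were taller than isolated ones by a median of 8 reads. If this came from single sites split into several intervals, merging peaks closer than 1 kb should end it. The test cannot decide: the difference after merging was 7 reads, nearly as large, and it missed the threshold (permutation p = 0.0681) with 417 clustered peaks left of 583. The test had been set on the p-value alone, which also rises when fewer peaks are compared. Merging kept the tallest interval of each group, with its enrichment, so it was not neutral to either measure. The median enrichment of clustered peaks was higher both before merging (60.1 against 55.1, permutation p = 0.0431) and after it (63.0 against 55.4, permutation p = 0.00414), but missed the threshold within 50 kb (57.3 against 55.1, permutation p = 0.254) and among peaks at or above the median enrichment (91.6 against 86.0, permutation p = 0.266). Without peaks narrower than 500 bp the medians were 62.9 and 55.3 (permutation p = 0.0012).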
